A study of Homo sapiens with 16 samples.

How the data were processed

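The series holds 12 RNA-seq libraries and 4 chromatin immunoprecipitation or input libraries of the human fetal osteoblast line hFOB, of which the latter 4 were not analysed here. Per the labels' protocols, cells were transfected with 50 nM siRNA and analysed 48 hours later, after starvation without serum and 1 hour with or without 5 nM BMP-2. The starvation time is given as 3 hours in the series' design text and as 4 hours in the treatment protocol. Per the labels' protocols, polyadenylated RNA from 500 ng of total RNA was made into stranded libraries with 10 cycles of PCR and sequenced as 75 base read pairs. Each condition was described as 3 biological replicates. Per the submitters' processing notes, STAR 2.5.3a, edgeR and the build GRCh38 were used. The gene counter, the annotation and the gene filter were not given in the sources used here.

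The authors deposited 1 table of 13589 gene symbols with CPM values (counts over a scaled library size) in 12 columns, together with fold changes, p-values and false discovery rates of their own comparisons. Column names equal the sample titles, and 0 columns of per-sample values were left unused. Each library's deposited CPM values were whole multiples of what 1 read is worth, for 100% of values at a tolerance of 0.01 reads, so reads per gene could be recovered, 11192713 to 18120745 per library. The sums of the deposited CPM values ranged from 965606 to 1040985. Every deposited gene had more than 1 CPM in at least 1 library, and 30 genes had it in exactly 1. The 10 most abundant genes took 3.97% to 4.82% of the reads of a library. Limits set by 3 reads, 0.165 to 0.276 CPM, cover counting error only, since reads are not independent molecules.

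The authors' fold changes were taken as log2, since the deposited value of -2.76 for YAP1 cannot be a natural log when the lowest library lies -2.07 natural log units and -2.99 log2 units from the highest. The deposited false discovery rates equal a Benjamini-Hochberg adjustment of the deposited p-values within 3.4e-14. The deposited comparison named for BMP-2 and siRNA together was read as an interaction from its values. The column names do not say in which arm the siRNA and BMP-2 comparisons were made. Values from the authors' deposited table carry no error or n of their own here. Of the symbols, 12644 were current in the RefSeq annotation of GRCh38.p14, 783 were older symbols and 162 matched neither. Gene positions are from that annotation.

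In the contrasts reported, samples were grouped by the siRNA and treatment labels, and replicates were numbered in accession order. A chi-square statistic per degree of freedom over genes was at least 2.63 for pairs of libraries with the same labels, so no pair was within sampling noise. After the values were seen, 4 libraries were also set against the other 8 by their scores on the second principal component, in ranges of genes weighted on it, a limma fit without the 4 and 3 tests of explanations. That selected libraries by a measured outcome, so it was withdrawn and its results are not used. Because targeted genes contradicted the labels, libraries are named by label and the authors' comparisons are reported as theirs. Contrasts between labelled groups were fitted with limma 3.58.1 in R 4.3.3 on log2(CPM + 0.5) of the 13398 genes with at least 1 CPM in at least 3 libraries. All 12 libraries shared 1 estimate of the spread with an intensity trend, leaving 8 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes on this scale understate changes of genes with low values. The 5 contrasts were siRNA without and with BMP-2, BMP-2 in each siRNA arm, and their difference.

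Gene lists, 28 in all, were fixed before the data were examined, and those with at least 5 measured members were tested. Labelled contrasts used camera in limma with a preset inter-gene correlation of 0.01, beside an estimated correlation and fry, adjusted over all lists and contrasts. The deposited comparisons used pre-ranked camera in limma on z values made from the deposited p-values and signs, adjusted over 26 lists and 3 comparisons. An estimated correlation needs the libraries behind the authors' comparisons and was not run there, so a preset of 0.05 and ranks were tried instead. With ranks, 4 further list and comparison pairs passed. These were interferon response genes as higher in the BMP-2 comparison (adjusted p 0.0281) and 3 lists as lower in the interaction. A list's count adjusted over the list alone applies Benjamini-Hochberg to its members only.

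Genes were to be named by a rule fixed before the data were examined: in each contrast the 10 largest rises and 10 largest falls past the threshold with a mean of at least 1 CPM, without clone names and with groups that did not overlap, up to 4 members per list, and always YAP1, WWTR1, CYR61, CTGF, ANKRD1, ID1, ID2, ID3, SMAD6 and SMAD7 in the contrasts they bear on. For the difference of BMP-2 effects it took the 3 genes of each sign with the smallest unadjusted p. Since the labelled contrasts called 0 genes, the rule was applied to the authors' deposited table with changes made after the values were seen. The condition on overlap was dropped, and the mean of at least 1 CPM was taken over all 12 libraries instead of in either group compared. List members named in the text that are not among its 4 largest were also chosen after their values were seen.

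Simulated counts had the means and library sizes of these libraries, with a change put into the siRNA contrast without BMP-2. On them limma called 50% of genes changed 1.5-fold, 90.9% of those changed 2-fold and 100% of those changed 4-fold. It also called 12 unchanged genes, with 13249 genes tested. The simulation gave every gene the same spread beyond counting error and kept each group to 1 condition. In the labelled groups YAP1 had a standard error of 1.06 on the log2 scale in that contrast. These rates therefore do not carry over to genes that split within the labelled groups. Pre-ranked camera on 13589 simulated z values with 1 of 26 lists shifted called that list and 0 others. Alternatives covered the pseudocount, the filter, scaling, the fitted libraries, the trend, robust moderation, library weights and leaving out each library. Voom on recovered reads and the settings for the deposited comparisons were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.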

Results

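RNA sequencing was used to measure gene expression in hFOB cells, a human fetal osteoblast line immortalised with a temperature-sensitive viral antigen. The cells received either scrambled siRNA or a pool of siRNAs against YAP1 and WWTR1, the genes of the transcriptional coactivators YAP and TAZ that carry the output of the Hippo pathway. They were then kept without or with 5 nM BMP-2, a bone morphogenetic protein that acts through SMAD1 and SMAD5, for 1 hour. The design had 4 labelled groups of 3 libraries, 12 in all, described as biological replicates. The reads recovered from the deposited CPM values ranged from 11192713 to 18120745 per library over 13589 genes. With 3 reads as the floor, the limit of detection ran from 0.165 to 0.276 CPM across the libraries, counting error only. The 4 libraries of SMAD1 chromatin immunoprecipitation and input were not analysed here. The comparisons asked how the siRNA changed the transcriptome, which genes responded early to BMP-2, and whether the BMP-2 response depended on YAP and TAZ.

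The targeted genes went against the labels. YAP1 (chromosome 11, 102110447 to 102233424, GRCh38) lay between 201.5 and 242.1 CPM in 6 libraries and between 30.5 and 40.9 CPM in the other 6, and each labelled group held both kinds. In the group labelled scrambled siRNA without BMP-2, YAP1 was at 242 CPM in replicate 1, 34.1 CPM in replicate 2 and 230 CPM in replicate 3. In the group labelled YAP/TAZ siRNA without BMP-2, the libraries had 35.9, 237 and 34.7 CPM. The libraries labelled scrambled siRNA with BMP-2 had 227, 40.9 and 205 CPM, and those labelled YAP/TAZ siRNA with BMP-2 had 31.7, 202 and 30.5 CPM. WWTR1 (chromosome 3, 149517235 to 149724788) split in the same places, with 6 libraries at 79.7 to 93.8 CPM and 6 at 19.5 to 28.9 CPM. So did CYR61, now named CCN1 (chromosome 1, 85580761 to 85583950), a matricellular gene used as a readout of YAP and TAZ, with a gap between 62.2 and 241 CPM. The widest gap in YAP1 was 4.92-fold.

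Direct BMP target genes went against the BMP-2 labels as well. ID1 (chromosome 20, 31605289 to 31606510), an inhibitor of basic helix-loop-helix factors and an immediate SMAD1/5 target, lay between 19.7 and 35.5 CPM in 6 libraries and between 152 and 243 CPM in the other 6. Among the libraries labelled without BMP-2, replicate 3 of the scrambled siRNA group had 199 CPM and replicate 1 of the YAP/TAZ siRNA group had 152 CPM. Among those labelled with BMP-2, replicate 3 of the scrambled siRNA group had 19.7 CPM and replicate 1 of the YAP/TAZ siRNA group had 21.1 CPM. ID2, ID3 and SMAD7, the last an inhibitory SMAD, each had 6 libraries on either side of their widest gaps, which were 2.30-fold, 2.18-fold and 2.88-fold. The widest gap of SMAD6, 1.47-fold, lay elsewhere, with 1 library below and 11 above it. Yet SMAD6 followed the sides of the ID1 gap without overlap. It was at 8.71 to 10.38 CPM in the libraries above that gap and 4.37 to 8.17 CPM in those below. In total, 4 of the 12 libraries lay on the side of the YAP1 gap opposite to their siRNA label, and 4 lay on the side of the ID1 gap opposite to their BMP-2 label. In accession order, each of the 8 libraries with another 4 places before it lay on the same sides of the YAP1 and ID1 gaps as that library, whereas the labels run in blocks of 3. The libraries were not regrouped by these values. Statements below about a group therefore concern the libraries labelled as such, and the comparisons the authors deposited are reported separately as theirs.

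**Figure D1:**
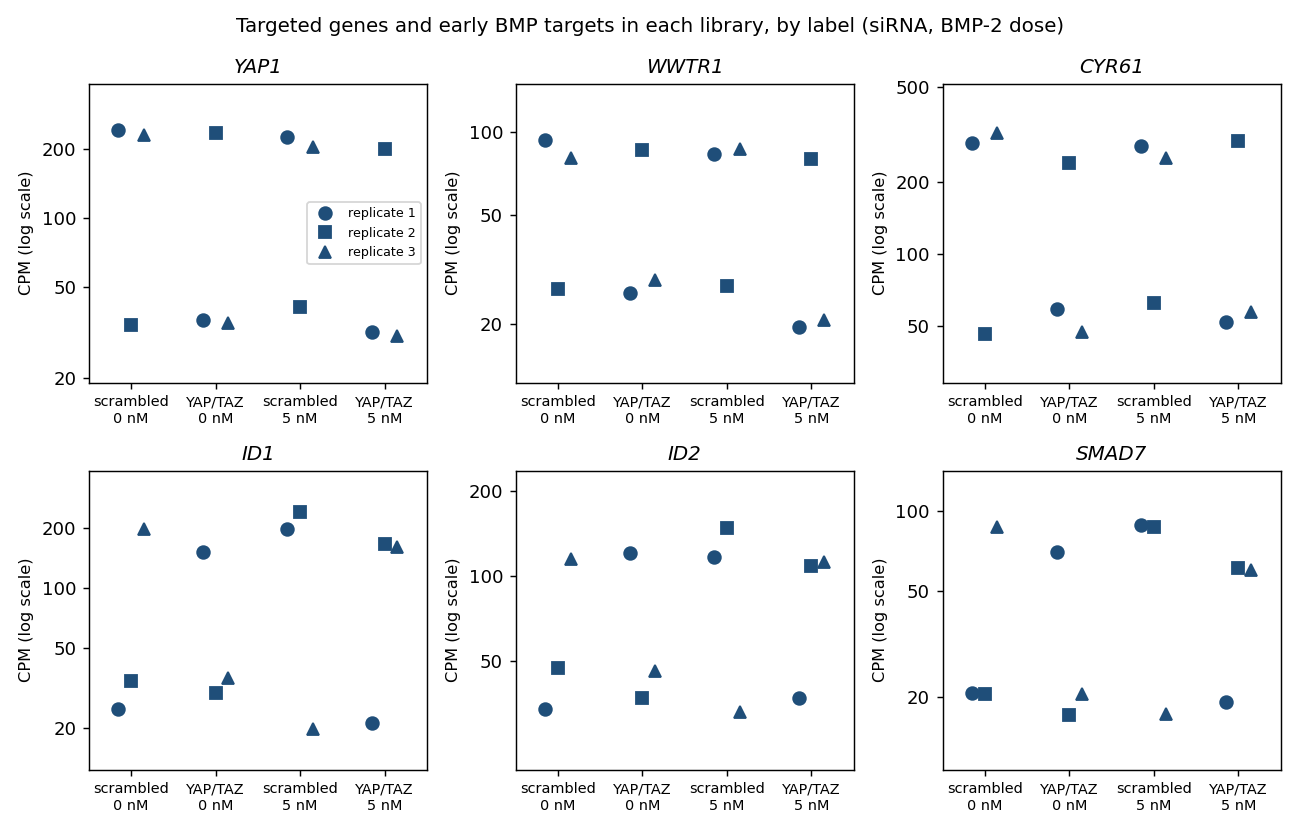
CPM on a log axis of YAP1, WWTR1, CYR61, ID1, ID2 and SMAD7 in each of the 12 libraries, placed by the labelled siRNA and BMP-2 dose, with 1 point per library and the marker giving the replicate. Each labelled group holds libraries from both levels of every gene shown, such as 242 and 34.1 CPM of YAP1 in the group labelled scrambled siRNA at 0 nM.

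The siRNA comparison in the authors' deposited table covered 13589 genes, of which 4795 had an FDR under 0.05, 2252 higher and 2543 lower. With the further condition of an absolute log2 fold change of at least 1, the authors' deposited table held 428 higher and 141 lower genes. The siRNA targets fell in the authors' deposited table, YAP1 by 2.76 (FDR 1.13e-09) and WWTR1 by 1.82 (FDR 2.03e-07) on the log2 scale. Other strong falls in the authors' deposited table were NPPB, the natriuretic peptide B gene, at -4.57, ANKRD1, a cardiac ankyrin repeat protein and YAP target, at -3.28, NLRP10 at -3.24 and LINC01111 at -3.05. The oxytocin receptor gene OXTR at -2.86, the endothelin gene EDN1 at -2.58, ST6GALNAC5 at -2.48, B3GALT2 at -2.46 and CYR61 at -2.44 completed the 10 largest falls in the authors' deposited table. The largest rises in the authors' deposited table were PDK4, a kinase that restrains pyruvate dehydrogenase, at 5.31, and HGF, hepatocyte growth factor, at 3.76. SLCO2B1 at 3.24, SLC14A1 at 2.62, PRSS35 at 2.61, TMEM140 at 2.46 and KY at 2.44 came next in the authors' deposited table. The immediate early transcription factor gene EGR2 at 2.40, SLITRK6 at 2.35 and the death ligand gene TNFSF10 at 2.30 followed in the authors' deposited table. Several of these genes were near the detection floor: NPPB reached at most 4.12 CPM, PDK4 3.68 CPM and HGF 3.79 CPM in any library. The highest library values of NLRP10, ST6GALNAC5, SLCO2B1, SLC14A1, PRSS35, TMEM140, EGR2 and SLITRK6 were as low, from 3.03 to 4.74 CPM. The size of such folds depends on how the lowest values were handled. The column names do not say whether this comparison was made without BMP-2 or over both doses.

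YAP/TAZ-TEAD target genes fell together: 19 of 21 measured members fell and 1 rose in the authors' deposited table, the same counts when adjusted over the list alone. Besides ANKRD1 and CYR61, CTGF, now CCN2, a connective tissue growth factor, fell by 2.06 and TGFB2, a TGF-beta ligand, by 2.33 in the authors' deposited table. NT5E was the member that rose, by 0.25 in the authors' deposited table. Pre-ranked camera in limma on the deposited values gave an adjusted p of 4.48e-11 for this list. Hippo pathway components and TEAD factors also fell, with 13 of 27 lower and 0 higher in the authors' deposited table, and the same counts adjusted over the list alone. WWC1 at -1.83, AJUBA at -1.21, TEAD4 at -0.84 and NF2 at -0.63 were among them in the authors' deposited table, and camera in limma gave an adjusted p of 5.73e-06.

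Actin cytoskeleton and SRF target genes fell, with 20 of 26 members lower and 0 higher in the authors' deposited table and the same counts adjusted over the list alone (camera adjusted p 2.95e-11). The tropomyosin gene TPM1 at -0.95, the calponin gene CNN2 at -0.78, ACTN1 at -0.70 and SRF at -0.42 were examples in the authors' deposited table. Of the cell cycle genes, 22 of 37 fell and 1 rose in the authors' deposited table (24 and 2 adjusted over the list alone, camera adjusted p 1.62e-05). The falls were small, with AURKA at -0.52, CDC20 at -0.50 and MKI67 at -0.34 in the authors' deposited table, and the member that rose was PCNA at 0.15. Cholesterol synthesis genes fell, 14 of 21 with 0 higher in the authors' deposited table (15 adjusted over the list alone, camera adjusted p 5.47e-06), including SQLE at -0.54. Ribosomal protein genes fell, 18 of 25 with 0 higher in the authors' deposited table (19 adjusted over the list alone, camera adjusted p 2.27e-06), by a median of 0.18 on the log2 scale. Glycolysis and hypoxia genes were lower in 16 and higher in 3 of 27 in the authors' deposited table (17 and 3 adjusted over the list alone). HK2 was at -0.99 and VEGFA at 0.60 in the authors' deposited table. The camera adjusted p of this list was 0.00777 and became 0.105 with a preset inter-gene correlation of 0.05.

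Interferon response genes rose: 24 of 29 were higher and 0 lower in the authors' deposited table (26 adjusted over the list alone, camera adjusted p 1.45e-08). IFI44L at 1.97, BST2 at 1.81, OAS2 at 1.36 and MX1 at 1.20 were examples in the authors' deposited table. Targets of p53 rose, with 17 of 20 higher and 1 lower in the authors' deposited table, the same counts adjusted over the list alone (camera adjusted p 1.19e-09). They included GDF15 at 1.66, the cyclin-dependent kinase inhibitor gene CDKN1A at 1.48, BBC3, a mediator of apoptosis, at 1.30 and MDM2 at 1.20 in the authors' deposited table. The exception was PLK2, at -0.39 in the authors' deposited table. Inflammatory NF-kB target genes were higher in 8 and lower in 1 of 21 in the authors' deposited table, the same counts adjusted over the list alone, with PTGS2 at 1.20 and ICAM1 at 0.96. The camera adjusted p of this list was 0.00986 and became 0.103 with a preset inter-gene correlation of 0.05.

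The remaining lists had members on both sides or few members past the threshold, and none passed the camera test. Early BMP/SMAD1/5 target genes were higher in 4 and lower in 4 of 29 in the authors' deposited table (3 and 4 adjusted over the list alone, camera adjusted p 0.739), with the BMP antagonist gene NOG at -1.40. BMP ligands, receptors and signal transducers were higher in 5 and lower in 6 of 24 in the authors' deposited table (5 and 7 adjusted over the list alone, camera adjusted p 0.849), with RGMB at -1.03. TGF-beta/SMAD2/3 responsive genes were higher in 8 and lower in 4 of 19 in the authors' deposited table (9 and 4 adjusted over the list alone, camera adjusted p 0.32), with TGFB3 at 1.32. Osteoblast differentiation genes were higher in 2 and lower in 3 of 14 in the authors' deposited table, the same counts adjusted over the list alone (camera adjusted p 0.977). Of these, the alkaline phosphatase gene ALPL was at -1.52 and ANKH, a pyrophosphate transporter gene, at 1.16 in the authors' deposited table. Extracellular matrix genes were higher in 9 and lower in 6 of 31 in the authors' deposited table, the same counts adjusted over the list alone (camera adjusted p 0.189), with MMP2 at 0.92 and LOX at -0.86. Immediate early genes were higher in 9 and lower in 6 of 28 in the authors' deposited table (10 and 7 adjusted over the list alone, camera adjusted p 0.585), with NR4A2 at 2.03 and JUN at -0.73. Focal adhesion and integrin genes were higher in 7 and lower in 10 of 25 in the authors' deposited table (8 and 10 adjusted over the list alone, camera adjusted p 0.874), with ITGA11 at 1.72 and FERMT2 at -0.90. Wnt pathway genes were higher in 3 and lower in 4 of 20 (3 and 6 adjusted over the list alone), Notch pathway genes in 2 and 0 of 13, and unfolded protein and amino acid stress genes in 2 and 6 of 22 in the authors' deposited table, the last 2 unchanged when adjusted over the list alone. Their camera adjusted p values were 0.913, 0.585 and 0.327.

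Some markers of other cell types also passed the threshold in the siRNA comparison, where 35.3% of all genes did in the authors' deposited table. In the authors' deposited table, epithelial markers were lower in 3 and higher in 0 of 6, with KRT7 at -1.14, and skeletal muscle markers were lower in 2 and higher in 1 of 12, with MYF5 at -1.35. Chondrocyte markers were higher in 1 and lower in 1 of 6, adipocyte markers in 3 and 1 of 7, endothelial markers in 2 and 1 of 10, and neural markers in 1 and 1 of 8 in the authors' deposited table. Adjusted over the list alone the counts were the same, apart from 0 lower chondrocyte and 0 lower neural markers in the authors' deposited table. Their camera adjusted p values were 0.122 for epithelial, 0.916 for skeletal muscle, 0.849 for chondrocyte, 0.287 for adipocyte, 0.637 for endothelial and 0.985 for neural markers. Of the 4 measured blood cell markers, too few to test, 2 were higher in the authors' deposited table, CD68 at 0.57 and LAPTM5 at 0.85. Mitochondrially encoded genes were not analysed here.

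**Figure D2:**
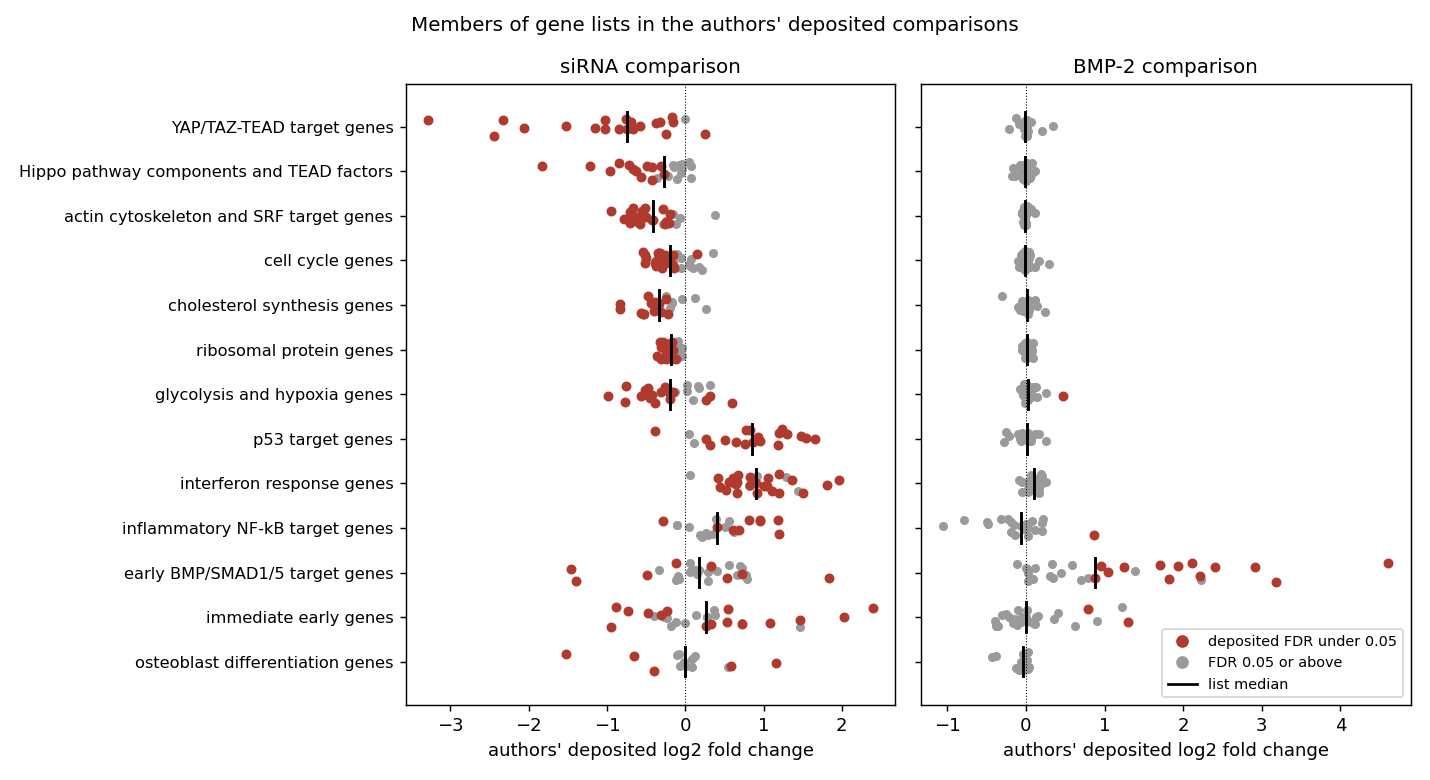
Log2 fold change of each measured member of 13 gene lists in the authors' deposited siRNA comparison (left) and BMP-2 comparison (right), 1 point per gene, red where the deposited FDR was under 0.05 and grey otherwise, with a black bar at the list median. Points are spread vertically only for visibility. In the siRNA comparison 19 of 21 YAP/TAZ-TEAD targets fell and 17 of 20 p53 targets rose, and in the BMP-2 comparison 13 of 29 early BMP/SMAD1/5 targets rose.

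The BMP-2 comparison in the authors' deposited table held 33 genes with an FDR under 0.05, of which 30 were higher and 3 lower. HES1 (chromosome 3, 194136148 to 194138732), a transcriptional repressor known from Notch signalling, rose most in the authors' deposited table, by 4.61 on the log2 scale (FDR 3.04e-05). The homeobox genes DLX2 and DLX3 rose by 3.18 and 2.22, and SNAI1 and SNAI2, repressors linked to epithelial-mesenchymal transition, by 2.41 and 0.95 in the authors' deposited table. The inhibitor genes ID1, ID3 and ID2 rose by 2.92, 1.82 and 1.71 in the authors' deposited table, with FDRs of 1.01e-05, 0.000306 and 4.43e-06. SMAD7 rose by 2.11, KLF10 by 1.94 and the cytokine signalling inhibitor gene SOCS3 by 1.73 in the authors' deposited table. SMAD6, the other inhibitory SMAD, was at 0.70 with an FDR of 0.272 in the authors' deposited table, on 4.37 to 10.4 CPM across the libraries. The 3 genes that fell in the authors' deposited table were RMRP, a non-coding RNA gene, at -1.84, STC1, the stanniocalcin gene, at -0.35 and CITED2 at -0.31.

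Early BMP/SMAD1/5 target genes supplied 13 of the 30 rises in the authors' deposited table, out of 29 measured members, with 0 falls. Adjusted over the list alone, 19 members were higher. Pre-ranked camera in limma gave an adjusted p of 1.01e-62 for the list, and 1.39e-33 with a preset inter-gene correlation of 0.05. NOG at 1.05, JUNB at 1.25 and GATA2 at 0.88 were further members that rose in the authors' deposited table. ID4, at 2.23 with an FDR of 0.358, and DLX5, at 1.39 with an FDR of 1, did not pass in the authors' deposited table. Of the immediate early genes, DUSP1 at 1.30 and IER2 at 0.79 rose and 26 of 28 did not pass in the authors' deposited table (3 higher and 3 lower adjusted over the list alone, camera adjusted p 0.327). BHLHE40 at 1.15 and SKIL at 0.68 rose among 19 TGF-beta/SMAD2/3 responsive genes in the authors' deposited table (2 adjusted over the list alone, camera adjusted p 0.0632). NFKBIA at 0.86 was the 1 riser of 21 inflammatory NF-kB targets, and PFKFB3 at 0.47 of 27 glycolysis and hypoxia genes, in the authors' deposited table. In the other 21 tested lists and the blood cell markers, 0 members passed at an FDR of 0.05 in the authors' deposited table, YAP/TAZ-TEAD targets (0 of 21) and osteoblast differentiation genes (0 of 14) included.

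The comparison named for BMP-2 and siRNA together was read as the interaction, since YAP1 was at 0.14 and ID1 at -0.32 there in the authors' deposited table. In it, 0 genes had an FDR under 0.05 and 281 of 13589 had an unadjusted p under 0.05 in the authors' deposited table. That share lies below 0.05, so the count alone is no sign of an effect. The early BMP targets ID1, ID2, ID3 and SMAD7 were at -0.32, -0.18, -0.22 and -0.27, each with an FDR of 1 in the authors' deposited table. HES1 and DLX2, which rose most in the BMP-2 comparison, were at -0.72 and -0.78 and did not pass either. These genes were picked after their values were seen. Across the 29 early BMP/SMAD1/5 target genes the interaction median was -0.18 in the authors' deposited table. Camera in limma gave this list an adjusted p of 0.132, or 0.0478 with ranks in place of z values. With a preset inter-gene correlation of 0.05 the camera adjusted p was 0.454. With ranks, extracellular matrix and interferon response genes also passed as lower in the interaction, each at an adjusted p of 0.0281 against 0.0809 and 0.122 with z values. Genes with the smallest unadjusted p were STC1 at 0.37, ZNF544 at 0.51 and ENOPH1 at 0.25, and C19orf60 at -0.59, DNAAF3 at -1.73 and ZNF658B at -1.91, none passing in the authors' deposited table.

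The contrasts of the groups as labelled called 0 single genes by limma with equal library weights over all 12 libraries. For YAP/TAZ against scrambled siRNA without BMP-2, YAP1 had a mean of 102 ± 116 CPM (SD, n = 3) in the libraries labelled YAP/TAZ siRNA and 169 ± 117 CPM (SD, n = 3) in those labelled scrambled. Its log2 fold change was -0.89 with a standard error of 1.06, and WWTR1 had -0.55 with a standard error of 0.69, both smaller than the spread between libraries of the same label. Leaving out replicate 2 of the group labelled scrambled gave -1.81 for YAP1 and -1.105 for WWTR1, and leaving out replicate 2 of the group labelled YAP/TAZ gave -1.80 and -1.09. Leaving out replicate 1 or 3 of either group gave -0.41 to -0.45 for YAP1 and -0.21 to -0.33 for WWTR1, and library weights gave -2.17 and -1.29 (limma adjusted p 0.0659 and 0.0687). CYR61 was at -0.90, CTGF at -0.78 and ANKRD1 at -0.97 on the log2(CPM + 0.5) scale. Leaving out each library in turn gave -1.80 to -0.41, -1.50 to -0.42 and -2.15 to -0.33, the lowest without replicate 2 of the group labelled scrambled, and library weights gave -2.09, -1.71 and -2.43. With limma and Benjamini-Hochberg adjustment, 0 of 13398 genes passed, 2.21% had an unadjusted p under 0.05 and the smallest adjusted p was 0.978. Camera with a preset correlation called YAP/TAZ-TEAD targets, actin cytoskeleton and SRF targets and cholesterol synthesis genes lower (adjusted p 0.00708, 0.00131 and 0.0362). With an estimated correlation camera gave each an adjusted p of 0.997, as it gave every list in every contrast. That correlation was estimated from the spread within labelled groups, which mix both levels of YAP1 and of ID1. It therefore cannot decide on any single call.

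With BMP-2, YAP1 had a mean of 87.9 ± 98.4 CPM (SD, n = 3) in the libraries labelled YAP/TAZ siRNA and 158 ± 102 CPM (SD, n = 3) in those labelled scrambled. The log2 fold change was -1.09 with a standard error of 1.06 for YAP1, -0.86 with 0.69 for WWTR1, and -0.77, -0.75 and -1.22 for CYR61, CTGF and ANKRD1. Without replicate 2 of the group labelled scrambled YAP1 was at -1.88, without replicate 2 of the group labelled YAP/TAZ at -1.98, and without replicate 1 or 3 of either at -0.63 to -0.73. Leaving out each library in turn gave -1.51 to -0.51 for WWTR1, -1.59 to -0.33 for CYR61, -1.44 to -0.39 for CTGF and -2.03 to -0.71 for ANKRD1, the lowest without replicate 2 of the group labelled YAP/TAZ. By limma 0 genes passed, 784 (5.85%) had an unadjusted p under 0.05 and the smallest adjusted p was 0.83. With library weights in limma 5486 genes passed, among them YAP1 at -2.52 (adjusted p 0.00459), WWTR1 at -1.79 (adjusted p 0.00323), CYR61 at -2.05, CTGF at -1.74 and ANKRD1 at -2.41. These weights were 0.33 and 0.30 for replicate 2 of the groups labelled scrambled and YAP/TAZ, the libraries on the side of the YAP1 gap opposite to their label, and 0.54 to 4.11 for the other 4 compared. The calls therefore rest on a setting that largely sets aside libraries that contradict the labels. Without replicate 3 of the group labelled scrambled siRNA with BMP-2 67 genes passed. YAP/TAZ-TEAD targets were called lower and skeletal muscle markers higher by camera, both at an adjusted p of 0.0194. With an estimated correlation camera gave both an adjusted p of 0.997, as it gave every list. The mean log2 deviation of the skeletal muscle list was 0.30, 0.46 and 0.29 in replicates 1, 2 and 3 of the group labelled YAP/TAZ siRNA with BMP-2. It was -0.31, -0.28 and 0.37 in those labelled scrambled siRNA with BMP-2, so replicate 3 of that group was as high as the libraries it was compared with.

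For BMP-2 against none in the libraries labelled scrambled siRNA, ID1 had a mean of 154 ± 118 CPM (SD, n = 3) with BMP-2 and 86.0 ± 97.7 CPM (SD, n = 3) without. Its log2 fold change was 0.82 with a standard error of 1.15, and ID2, ID3, SMAD6 and SMAD7 had 0.54, 0.50, -0.06 and 0.61. Leaving out each library in turn gave 0.18 to 1.97 for ID1, 0.13 to 1.20 for ID2, 0.09 to 1.25 for ID3, -0.28 to 0.30 for SMAD6 and 0.21 to 1.38 for SMAD7. The highest came without replicate 3 labelled with BMP-2, and without replicate 3 labelled without BMP-2 ID1 was at 1.74. By limma 0 genes passed, 271 (2.02%) had an unadjusted p under 0.05 and the smallest adjusted p was 1. Camera called interferon response genes lower (adjusted p 8.64e-08) and ribosomal protein genes higher (adjusted p 0.00606). With an estimated correlation camera gave each an adjusted p of 0.997, as it gave every list. In replicates 1, 2 and 3 labelled with BMP-2, the interferon list's mean log2 deviation from its 12-library average was -0.20, 0.33 and -1.06. It was 0.05, 0.75 and -0.02 in those labelled without. Replicate 3 labelled with BMP-2 lay below the ID1 gap, and replicate 3 labelled without lay above it. The authors' deposited BMP-2 comparison had this list higher, with a median of 0.10 and a camera adjusted p of 0.189 (0.0281 with ranks). The call of lower interferon genes therefore cannot be read as a BMP-2 response.

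In the libraries labelled YAP/TAZ siRNA, ID1 had a mean of 116 ± 82.2 CPM (SD, n = 3) with BMP-2 and 72.3 ± 68.8 CPM (SD, n = 3) without, a log2 fold change of 0.60 with a standard error of 1.15. ID2, ID3, SMAD6 and SMAD7 had 0.37, 0.16, 0.31 and 0.49. With each library left out in turn, ID1 ranged over 0.10 to 1.58 and the others over 0.04 to 0.89 for ID2, -0.16 to 0.77 for ID3, 0.23 to 0.44 for SMAD6 and 0.12 to 1.12 for SMAD7. ID1 was highest without replicate 1 labelled with BMP-2, and at 1.33 without replicate 1 labelled without BMP-2. By limma 0 genes passed, 1286 (9.6%) had an unadjusted p under 0.05 and the smallest adjusted p was 0.17. In a fit to the 6 libraries compared 25 genes passed, with library weights 477, without replicate 3 of the group labelled scrambled siRNA with BMP-2 115, and without replicate 2 of the group labelled YAP/TAZ siRNA with BMP-2 1. Skeletal muscle markers and glycolysis and hypoxia genes were called higher by camera, at adjusted p values of 0.00172 and 0.045. With an estimated correlation camera gave each an adjusted p of 0.997, as it gave every list. The skeletal muscle list was at -0.16, -0.35 and -0.37 in the libraries labelled YAP/TAZ siRNA without BMP-2. Its higher level in those labelled YAP/TAZ siRNA with BMP-2 was shared by replicate 3 of the group labelled scrambled siRNA with BMP-2, at 0.37. That library also stood with them on the second principal component at -17.4. These libraries come last of the RNA-seq libraries in accession order, and among them lie all combinations of sides of the YAP1 and ID1 gaps. The skeletal muscle call therefore cannot be read as a BMP-2 response.

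The difference of the BMP-2 effect between the libraries labelled YAP/TAZ siRNA and those labelled scrambled was -0.22 with a standard error of 1.62 for ID1 and -0.17, -0.34, 0.37 and -0.11 for ID2, ID3, SMAD6 and SMAD7. Leaving out each library in turn gave -1.37 to 0.75 for ID1, -0.83 to 0.35 for ID2, -1.10 to 0.28 for ID3, 0.002 to 0.58 for SMAD6 and -0.88 to 0.52 for SMAD7, with the lowest of ID1, SMAD6 and SMAD7 without replicate 3 of the group labelled scrambled siRNA with BMP-2. CYR61, CTGF and ANKRD1 had 0.12, 0.03 and -0.25. The genes with the smallest unadjusted p in limma were LPPR3 at 1.41, CORO6 at 0.86 and JUND at 0.48, and DNER at -0.51, FUT8 at -0.38 and CDK7 at -0.43. By limma 0 genes passed, 365 (2.72%) had an unadjusted p under 0.05 and the smallest adjusted p was 1. Without replicate 3 of the group labelled scrambled siRNA with BMP-2 10 genes passed, among them LPPR3 at 1.62 (adjusted p 0.0459). Skeletal muscle markers were called higher by camera at an adjusted p of 0.000229. With an estimated correlation camera gave them an adjusted p of 0.997, as it gave every list. As above, the list was also high in replicate 3 of the group labelled scrambled siRNA with BMP-2. That library and those labelled YAP/TAZ siRNA with BMP-2 come last in accession order, so the call cannot be told apart from their position. Voom in limma on the recovered reads called 0 genes in each of the 5 contrasts. The labelled siRNA contrasts without and with BMP-2 had a Pearson correlation of 0.339 and a Spearman correlation of 0.351 across 13398 genes. The labelled BMP-2 contrasts in the arms labelled scrambled and YAP/TAZ siRNA had 0.391 and 0.323. Genes are not independent replicates. Each labelled group mixed both levels of YAP1 and of ID1, so these values do not measure how far siRNA or BMP-2 effects agree between arms.

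The 12 libraries separated along axes that crossed the labels. The first principal component, 53.1% of the variance over 13398 genes, ran from -23.3 to 27.3, and each labelled group had libraries at both ends, such as 21.1, -22.5 and 20.5 in replicates 1, 2 and 3 of the group labelled scrambled siRNA without BMP-2. On the second, 17.5% of the variance, the libraries labelled YAP/TAZ siRNA with BMP-2 were at -19.6, -17.5 and -17.6. Those labelled scrambled siRNA with BMP-2 were at 10.1, 6.9 and -17.4, and the scores of the libraries labelled without BMP-2 ran from 6.0 to 11.6. The libraries with negative scores on it come last of the RNA-seq libraries in accession order. No comparison of libraries chosen by these scores is reported. One was made and withdrawn, since it selected libraries by a measured outcome.

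**Figure D3:**
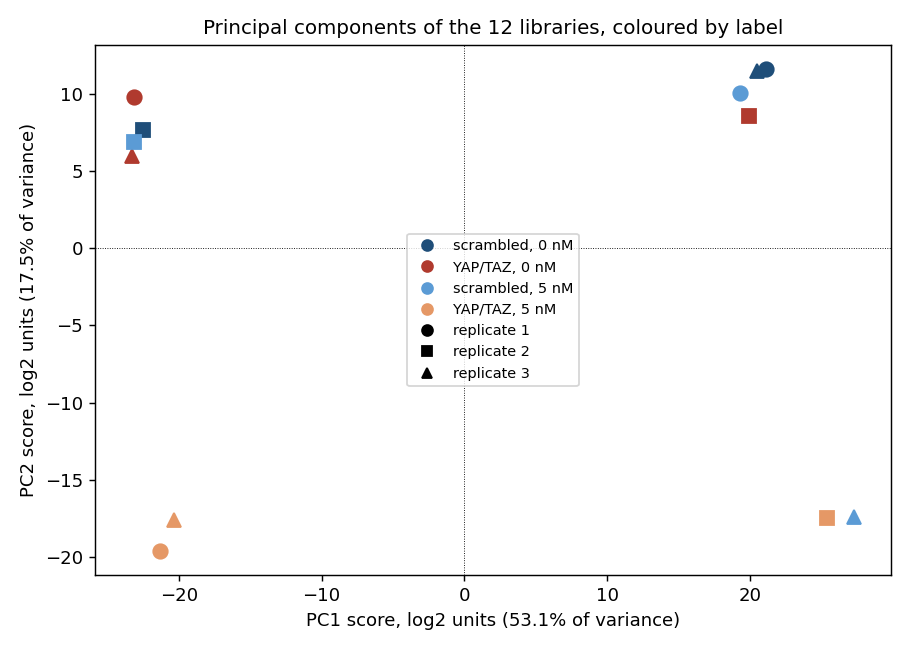
Scores of the 12 libraries on the first (x axis, 53.1% of variance) and second (y axis, 17.5%) principal components of log2(CPM + 0.5), in log2 units, coloured by labelled group with the marker giving the replicate. Libraries of each labelled group fall at both ends of the x axis, and y axis scores run from -19.6 to 11.6.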

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

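The settings for the authors' deposited table and voom on recovered reads were chosen after seeing the data. No paired analysis was possible because the labels of the RNA libraries carry no replicate numbers. The planned tests with edgeR and DESeq2 on recovered reads were not run, and agreement over called genes gave no value since 0 genes were called. Counts of called genes for the labelled contrasts were 0 under most settings, and the cause of the exceptions was not tested. Library weights were 0.30 to 0.37 for replicate 2 of every labelled group, the 4 libraries on the side of the YAP1 gap opposite to their label, so calls with weights do not support the labels. With library weights, 5486 genes (2704 higher, 2782 lower) passed for siRNA with BMP-2 and 477 for BMP-2 in the arm labelled YAP/TAZ siRNA. A fit to the 6 libraries compared gave 25 genes for the latter. Leaving out each library in turn gave 0 to 67 genes for siRNA with BMP-2, 0 to 115 for BMP-2 in the arm labelled YAP/TAZ siRNA and 0 to 10 for the difference of BMP-2 effects. The highest of each came without replicate 3 of the group labelled scrambled siRNA with BMP-2. In the other 2 contrasts it gave 0 to 0. Without replicate 2 of the group labelled YAP/TAZ siRNA with BMP-2, 1 gene passed for BMP-2 in that arm. The authors' deposited table gave 4795 genes for siRNA and 33 for BMP-2, against 0 from the labelled groups. In the authors' deposited table, an FDR under 0.01 left 2950 and 21 genes, and an absolute log2 fold change of at least 1 left 569 and 19.

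With library weights in siRNA with BMP-2, YAP1 reached a log2 fold change of -2.52 (limma adjusted p 0.00459) and WWTR1 -1.79 (limma adjusted p 0.00323), past the threshold in that setting only, as were CYR61, CTGF and ANKRD1. LPPR3 passed in the difference of BMP-2 effects without replicate 3 of the group labelled scrambled siRNA with BMP-2. Of the 10 list and contrast pairs called by camera with a preset correlation, 0 were called with an estimated correlation and 0 with fry, and 10 with median-ratio scaling. The estimated correlation and fry draw on the spread within labelled groups, which mix both levels of YAP1 and of ID1. Their counts of 0 therefore do not decide on these calls. For the authors' deposited table, 11 pairs passed at a preset correlation of 0.01, 9 at 0.05 and 15 with ranks. The correlation of the labelled siRNA contrasts was 0.695 with library weights and 0.108 to 0.533 leaving out each library. That of the labelled BMP-2 contrasts was 0.124 and 0.016 to 0.446. Both were lowest without replicate 3 of the group labelled scrambled siRNA with BMP-2. SMAD6 in BMP-2 against none in the arm labelled scrambled turned from -0.06 to 0.065 with library weights and ranged from -0.28 to 0.30 leaving out each library. ID3 in the arm labelled YAP/TAZ ranged from -0.16 to 0.77. In the difference of BMP-2 effects, CTGF turned from 0.03 to -0.033 with library weights and -0.034 with voom, and ANKRD1 from -0.25 to 0.017 with library weights. Leaving out each library there gave -1.37 to 0.75 for ID1, -0.83 to 0.35 for ID2, -1.10 to 0.28 for ID3, 0.002 to 0.58 for SMAD6 and -0.88 to 0.52 for SMAD7. The same gave -0.69 to 1.03 for CYR61, -0.66 to 0.75 for CTGF and -1.06 to 0.93 for ANKRD1. None of these genes passed the threshold in those settings.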

Other observations

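All tests of explanations in this part were chosen after the result was seen. Of the 33 genes called in the BMP-2 comparison, 15 had a siRNA value of the other sign and 18 of the same sign in the authors' deposited table. Of these, 10 and 7 had a siRNA FDR under 0.05 in the authors' deposited table. The genes named here were picked after the values were seen. EDN1 rose by 1.04 in the BMP-2 comparison and fell by 2.58 in the siRNA comparison of the authors' deposited table. NOG, which encodes the BMP antagonist noggin, was at 1.05 and -1.40, SOCS3 at 1.73 and -0.75, and GADD45B, a stress response gene, at 1.55 and -0.86 in the authors' deposited table. With the same sign in both, JUNB was at 1.25 and 0.73, NFKBIA at 0.86 and 0.82 and ID2 at 1.71 and 0.33 in the authors' deposited table. HES1 and DLX2 were at 0.78 and 0.79 in the siRNA comparison of the authors' deposited table, with FDRs of 0.265 and 0.12. In the interaction, EDN1, NOG, SOCS3 and GADD45B were at 0.10, 0.30, 0.11 and -0.36, each with an FDR of 1 in the authors' deposited table. HES1 and DLX2 were at -0.72 and -0.78 there, with deposited unadjusted p values of 0.242 and 0.11, and did not pass either. The column names do not say whether the siRNA and BMP-2 comparisons share control libraries. Of all contrasts of 3 libraries against 3, those that correlated best with each of these columns had the same 3 reference libraries.

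The split of YAP1 levels within each labelled group was weighed against 3 technical explanations. A knockdown that failed in some libraries is argued against, since 2 libraries labelled scrambled siRNA lay below the widest gap in YAP1. Library scaling is argued against too, since the highest and lowest sums of CPM differed 1.078-fold and the gap was 4.92-fold. The labels may not belong to the columns they are attached to: across 13589 genes the deposited siRNA log2 fold changes correlated at 0.602 with the labelled contrast without BMP-2 and at 0.53 with that with BMP-2. These were at least matched by 4253 and 5491 of the 18480 contrasts of 3 libraries against 3, the highest of which reached 0.976. For the deposited BMP-2 column the labelled contrasts gave 0.036 in the arm labelled scrambled and 0.205 in the arm labelled YAP/TAZ, at least matched by 8069 and 3448 contrasts, and the highest contrast 0.907, and the 2 highest contrasts had the same 3 reference libraries. Conditions repeating every 4 libraries in accession order, under labels in blocks of 3, may explain both this and the repeat of the YAP1 and ID1 sides in 8 of 8 libraries, which would change what each labelled contrast means. No condition was assigned from this.

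Other splits of the same libraries were counted for each labelled contrast. For siRNA without BMP-2, BMP-2 in the arm labelled scrambled and BMP-2 in the arm labelled YAP/TAZ, the labelled split and the highest other of 10 splits both gave 0 genes. For siRNA with BMP-2 the labelled split gave 0 genes and the highest other of 10 gave 1638, which points to a structure of the samples that the labels do not follow. That split set replicates 1 and 3 labelled scrambled siRNA and replicate 2 labelled YAP/TAZ siRNA against the others. Without BMP-2, the split of the same replicates also followed the sides of the YAP1 gap, yet gave 0 genes. All libraries shared 1 estimate of the spread, with labelled groups that mix both levels. A count of 0 in a split therefore does not argue against such a structure. For the difference of BMP-2 effects the labelled split and the highest other of 100 both gave 0 genes. No split can give fewer than 0 genes, so these counts say nothing about chance, and 10 splits are too few for a share under 0.05.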
